A study of Sphyracephala beccarii with 3 samples.

How the data were processed

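Genomic DNA of adult female and male Sphyracephala beccarii, a fly of the stalk-eyed family Diopsidae, was compared by comparative genomic hybridization (CGH) on 3 two-colour Agilent arrays. In this assay female and male DNA carry different fluorescent dyes and compete for the same probes, so the ratio of the dyes at a probe follows the relative dose of its target sequence. Per the labels' protocols, each DNA sample was a pool of flies from population cages founded in South Africa, the eyes and digestive tract were removed, the DNA was treated with RNase, cut with the restriction enzymes AluI and RsaI, and labelled with Cy3 or Cy5. Per the labels, female DNA carried Cy3 on replicates 1 and 3 and Cy5 on replicate 4, and the series' design text calls the 3 arrays biological replicates. All 3 arrays formed a single group in which each array set a female pool against a male pool.

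The deposited scanner files hold spot intensity values written by Agilent Feature Extraction 10.7.3.1, per the file headers: mean spot and median background intensities as scanned, and processed intensities that had been background-subtracted, detrended and scaled by a linear factor per dye. The same files give the log10 ratio of Cy5 over Cy3 and flags for each spot, per the file headers. The deposited series value table was compared with the scanner values and holds the log2 ratio of female over male DNA, already turned for dye, plus a constant per array of 0.2 for replicate 1, 0.15 for replicate 3 and 0.025 for replicate 4; 99.7%, 99.8% and 99.8% of its values lay within 0.01 of that relation. Its column medians were 0.090, 0.074 and 0.016, and the purpose of the constants is not given in the sources used here. The value table holds 65522 probes of 11953 contigs, 1058 contigs fewer than the array, and served only as an alternative.

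The array carries 71475 probes of 60 bases, each spotted 2 times, for 13011 contigs of the species' sequence assembly. The number of probes per contig was 6 for 10358 contigs and 1 for 85 contigs. Contig identifiers of 11817 contigs hold the letters CDS and those of 1194 contigs do not; the sources used here do not define the distinction. The files do not pair the contigs with gene names, gene functions or chromosomes, and no genome of the species was used. The lists of genes by Drosophila chromosome arm (Muller element) and by function that had been fixed before the data were examined were therefore not run, and at most 2 contigs that were higher and 2 that were lower in female DNA are named. The naming rule was reduced to these 4: the 2 highest and the 2 lowest mean ratios among contigs with adjusted p under 0.05, the same sign on all 3 arrays and at least 3 probes.

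The log2 ratio of female over male processed intensity was taken per spot, after removal of control spots and of the 7, 19 and 7 spots flagged as outliers on replicates 1, 3 and 4. Each array was centred on the median of its ratios, without loess or quantile normalization. The medians before centring were -0.11, -0.07 and -0.01. Spots of a probe were averaged, and probes were averaged per contig. Probes were kept if they were well above background in the female or the male channel on all 3 arrays, which removed 118 probes, and contigs with at least 2 such probes were tested, 12925 in all. Signals of a single channel, where given, are log2 processed intensities relative to the median probe of that channel. A fold given as a lower bound uses these per-channel signals, with a dim probe raised to the lowest signal called well above background, and is open to dye bias.

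Contig ratios were tested against 0 with limma 3.58.1 (lmFit with an intercept only, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested contigs. A contig was called female-high or male-high at adjusted p under 0.05 and a mean log2 ratio of at least 0.5 in size. With 3 arrays, p-values rest on a spread shared across contigs, and contigs are not independent of each other. A normal mixture of 2 components was fitted to the mean ratios with mclust 6.1.1. Probes were compared with each other by BLAST+ 2.17.0 (expectation value at most 1e-06); contigs joined by probe matches of at least 95% identity over at least 50 bases were called near-identical, and contigs whose closest match lay under 95% were called similar. Fisher's exact test and permutation tests were two-sided, except the shuffles of pairs and of probe order, which were one-sided. Intervals of shares are 95% exact binomial (Clopper-Pearson) intervals over contigs. The number of arrays limits the precision of every ratio.

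The calling steps were tested on simulated data for 12925 contigs, of which 50 had each of 4 true ratios. The number of contigs was that of the female against male comparison, and the spreads were those of its not-called contigs. At a true log2 ratio of 0.85, 80% of changed contigs were called, at -0.85 74%, at 0.6 64% and at -2 94%, with 0 of 12725 unchanged contigs called. The simulated noise was independent between arrays and held no dye effect. Far fewer contigs were changed than were called in the data, which makes the adjusted p harder to pass. The shares called therefore hold for that setting only and do not give the share missed in the data. The 0 false calls do not cover calls driven by dye. The mixture returned a mean of 0.851 for a simulated 0.85, in data without a male-high tail. Alternatives fixed before the data were examined were normexp background correction with an offset of 50, centring on the mode, the median over probes, at least 1 or at least 5 probes, no filter or a stricter filter on dim probes, a dye term, the deposited value table, other thresholds, moderated variances with a trend, a mixture of 3 components, and each replicate left out. All 3 arrays shared a slide, so no batch term could be fitted.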

Results

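The arrays measured the dose of 13011 contigs in female relative to male DNA of Sphyracephala beccarii. The series title gives the location of sex chromosome sequence and gene movement as the subject. Each array set 1 female pool against 1 male pool, with 3 arrays in all. Nearly all spots were well above background: 99.8%, 99.9% and 99.9% in the female channel and 99.6%, 99.8% and 99.8% in the male channel of replicates 1, 3 and 4. The median spread between the 2 spots of a probe was 0.026, 0.026 and 0.027 (SD, log2 ratio). Across contigs, which are not independent replicates, the ratios of replicates 1 and 3 correlated with r = 0.945, those of replicates 1 and 4 with r = 0.772, and those of replicates 3 and 4 with r = 0.812. 

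The first question was which contigs had a higher dose in female DNA, as sequence present 2 times in females and 1 time in males would. Of 12925 contigs tested, 2178 (16.9%) were female-high in limma at adjusted p under 0.05. Their ratios formed a separate peak, with a mean log2 ratio of 0.84 ± 0.06 (SD over 3 arrays) and a spread of 0.11 (SD) over contigs. The mean was 0.86 on replicate 1, 0.89 on replicate 3 and 0.77 on replicate 4. The 10667 contigs that were not called had a mean of -0.04 ± 0.04 (SD over 3 arrays) and a spread of 0.08 over contigs. The distance between the peaks was 0.88 ± 0.03 (SD, n = 3), or 1.84-fold, and was 0.90, 0.89 and 0.85 on the arrays in turn. The gap between the peaks was thinly filled: 26 contigs had a mean ratio between 0.3 and 0.5, and every contig at 0.5 or above passed the adjusted p.

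**Figure D1:**
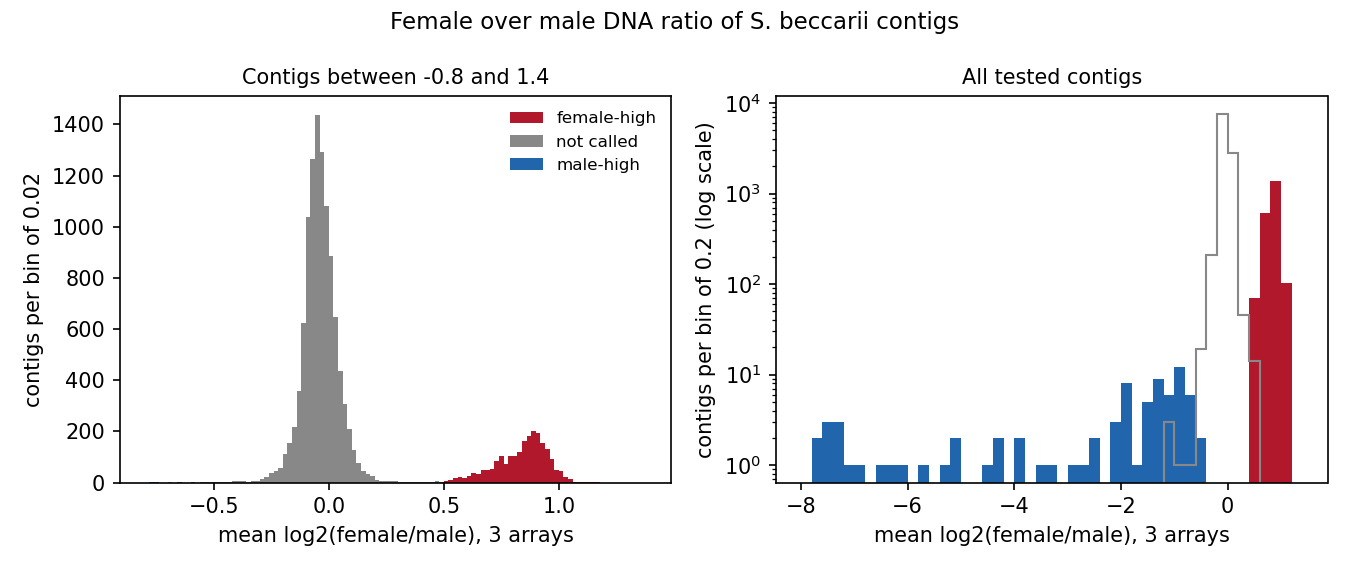
Number of contigs by mean log2 female over male ratio of 3 arrays, from -0.8 to 1.4 in bins of 0.02 (left, linear axis) and for all tested contigs in bins of 0.2 (right, log axis). Colours mark female-high (2178), not called (10667) and male-high (80) contigs, and the female-high contigs form a peak near 0.86 that is separate from the main peak.

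All 2178 female-high contigs were above 0 on each array, and 1972 of them were at 0.5 or above on each array. In 17 of them, 1 array lay under 0.3 while both others lay at 0.6 or above. The ratios of the female-high contigs ran from 0.63 (5th percentile) to 1.00 (95th percentile). The highest that met the naming rule were SbAss10_8027, at 1.17 ± 0.34 (SD, n = 3; adjusted p = 3.4e-04 in limma, 6 probes), and SbAss10_15049, at 1.16 ± 0.38 (SD, n = 3; adjusted p = 5.2e-04, 5 probes). Both were lower on replicate 4, where SbAss10_8027 measured 0.78 against 1.31 and 1.41, and SbAss10_15049 measured 0.77 against 1.17 and 1.53. The first probe of SbAss10_8027 has the sequence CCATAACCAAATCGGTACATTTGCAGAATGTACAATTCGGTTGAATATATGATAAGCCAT and a ratio of 1.67 ± 1.24 (SD, n = 3). The first probe of SbAss10_15049 has the sequence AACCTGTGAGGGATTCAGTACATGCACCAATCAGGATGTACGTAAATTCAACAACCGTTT and a ratio of 1.59 ± 1.17 (SD, n = 3). Each of these probes contains the RsaI site GTAC, and probes with such sites read higher where female DNA was in Cy3.

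The share of female-high contigs did not differ detectably between the kinds of identifier. They were 16.8% (1981 of 11793; 95% interval 16.1 to 17.5%) of tested contigs with CDS in the name and 17.4% (197 of 1132; 15.2 to 19.7%) of those without (Fisher's exact test, p = 0.618). The planned mixture of 2 normal components did not isolate the female-high peak. Its upper component had a mean of 0.53 and a share of 20.4%, because it was broad (SD 0.77) and took in 262 contigs with a ratio below 0. Fitted without contigs at -0.5 or lower, a restriction chosen after the data were seen, the upper component had a mean of 0.84, an SD of 0.12 and a share of 17.1%.

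The second question was which contigs had a higher dose in male DNA. Of the contigs tested, 80 (0.619%) were male-high in limma at adjusted p under 0.05, with a median log2 ratio of -1.65. They fell into a far group of 24 contigs at -3 or lower and 56 contigs above -3. All 80 were below 0 on each array, and 51 were at -0.5 or lower on each array. The naming rule took SbAss10_16750, at -7.61 ± 1.59 (SD, n = 3; adjusted p = 1.7e-04, 5 probes), and SbAss10_16746, at -7.61 ± 1.97 (SD, n = 3; adjusted p = 1.7e-04, 3 probes). These sizes are inexact and set no order, because part of the female signal was not well above background, and they moved with the background handling and the arrays used: with normexp they measured -5.34 and -5.59, without replicate 4 -8.52 and -8.73, and without replicate 1 -7.07 and -6.89. In female DNA, 1 of the 5 probes of SbAss10_16750 was well above background on replicate 1, 2 on replicate 3 and all 5 on replicate 4. For SbAss10_16746, 1 of 3 probes was well above background in female DNA on replicates 1 and 3, and all 3 on replicate 4. On replicate 4, where all their probes were well above background, SbAss10_16750 measured -5.78 and SbAss10_16746 -5.36. In 1 other contig every probe was not well above background in female DNA on any array, and the male signal was at least 6.69-fold higher, a bound that was not itself tested. Its measured ratio of -4.415 (adjusted p = 2.7e-06 in limma) rests on that dim female signal. All 423 probes of the male-high contigs were well above background in male DNA on all 3 arrays.

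**Figure D2:**
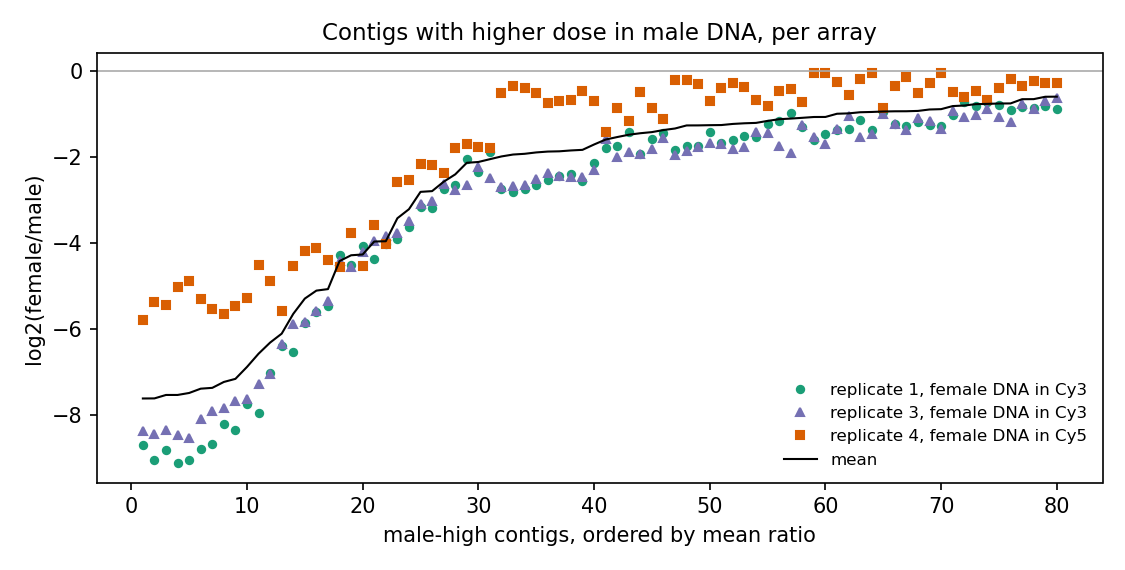
Log2 female over male ratio of the 80 male-high contigs on each array, ordered by their mean (black line). Points mark replicates 1, 3 and 4, and replicate 4, with female DNA in Cy5, lies closest to 0 for most contigs.

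Male-high contigs were concentrated among identifiers without CDS. They were 4.51% (51 of 1132; 95% interval 3.37 to 5.88%) of tested contigs without CDS in the name and 0.246% (29 of 11793; 0.165 to 0.353%) of those with it, an odds ratio of 19.1 (11.8 to 31.5; Fisher's exact test, p = 1.8e-34). The test treats contigs as independent, which near-identical contigs are not, so its p and the intervals are likely too small. In the far group, 12 of 24 contigs lacked CDS in the name. Male-high contigs were bright: 64 of 80 had a male signal more than 2 log2 units above the median probe, against 92 of 10667 contigs that were not called and 0 of 2178 female-high contigs. The male signal is part of the ratio that set the calls, so this contrast is partly built in. Many were near-identical to each other, and the 80 contigs made up 52 groups of near-identical sequence, the biggest with 10 male-high contigs. When near-identical contigs were counted once, an alternative chosen after the data were seen, 53 male-high groups were called. Of these, 62.3% lacked CDS in the name, and Fisher's exact test was not repeated on them. Replicate 4 limited the count: without it 129 contigs were called, and on it the 56 contigs above -3 averaged -0.67 ± 0.57 (SD over contigs), against -1.65 ± 0.68 and -1.74 ± 0.64 on replicates 1 and 3.

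The dye orientation was 2 to 1, so the ratios were also compared between orientations. The mean difference between the arrays with female DNA in Cy3 and the array with female DNA in Cy5 was 0.05 over contigs, with a spread of 0.29 (SD over contigs). Because each array was centred on its own median, this mean cannot show a dye effect shared by all contigs. Only the variation of the difference between contigs or probes can be read. Among contigs that were not called, the ratios of replicates 1 and 4 correlated with r = -0.702 across contigs, those of replicates 3 and 4 with r = -0.383, and those of replicates 1 and 3 with r = 0.558. Both the sites of the digest and the brightness of a contig went with this difference. Probes of not-called contigs with no AluI site (AGCT) or RsaI site (GTAC) averaged -0.12 ± 0.38 (SD over probes) in the difference. Probes with 1 site averaged 0.29 ± 0.48, those with 2 sites 0.63 ± 0.56 and those with 3 sites 0.88 ± 0.58. On single arrays, probes with 2 sites averaged 0.31 and 0.32 where female DNA was in Cy3 and -0.32 where it was in Cy5.

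**Figure D3:**
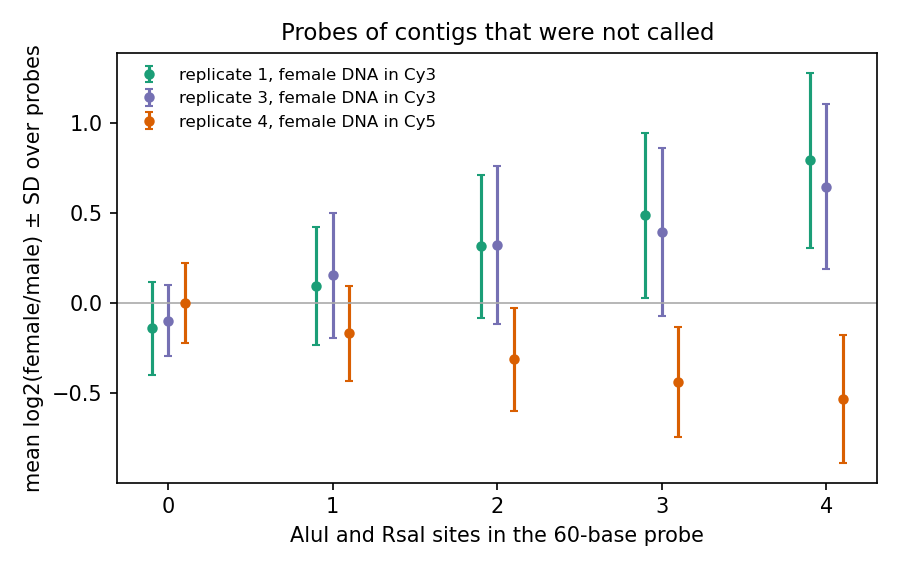
Mean log2 female over male ratio (± SD over probes) of probes of not-called contigs by the number of AluI and RsaI sites in the probe, for replicates 1, 3 and 4. The ratio is higher with more sites where female DNA was in Cy3 and lower where it was in Cy5.

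Sites occurred in 35.7% of female-high probes and 35.8% of not-called probes. Among female-high contigs, probes without a site averaged 0.78, 0.81 and 0.86 on replicates 1, 3 and 4, and probes with a site averaged 0.99, 1.04 and 0.63. For brightness, the 92 not-called contigs with a male signal more than 2 log2 units above the median probe averaged -0.53 ± 0.36 (SD over contigs) with female DNA in Cy3 and 0.49 ± 0.37 on replicate 4. In a fit with a dye term, which weights the orientations equally, all 80 male-high contigs were called again among 86, and the 56 above -3 averaged -1.18 in place of -1.35. The spread in that fit rests on replicates 1 and 3 alone, because the dye term fits replicate 4 exactly. The repeated calls therefore do not show that these contigs withstand dye bias.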

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

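Alternatives for the named contigs, the mean ratio of called female-high contigs, the percent without CDS and the dye difference were chosen after the data were seen. So were those on near-identical contigs, digest sites and a mixture without contigs at -0.5 or lower. The count of female-high contigs stayed within 1.5 times in all 17 alternatives, from 1900 with at least 5 probes (where 1900 of the 2178 were shared) to 2201 at adjusted p alone. The count of male-high contigs stayed within 1.5 times in 15 of 17, and was 53 with near-identical contigs counted once, since fewer units were then tested, and 77 to 129 with a replicate left out. Leaving out replicate 4 gave the 129. The 2-component mixture mean of 0.53 became 0.58 with normexp, 0.60 with mode centring, 0.55 with at least 5 probes, 0.60 with the authors' value table, 0.48 to 0.52 with a replicate left out, 0.84 with 3 components, 0.48 with probes without a digest site and 0.84 without contigs at -0.5 or lower. The mixture share of 20.4% became 16.9%, 21.6% and 17.1% in the last 3 of these, and 20.4 to 21.2% with a replicate left out. The mean ratio of called female-high contigs, 0.84, became 0.93 with normexp and 0.91 with mode centring, and was 0.82 to 0.88 with a replicate left out. The percent of male-high contigs without CDS, 63.8, became 46.6 at adjusted p alone and 51.9 at a log2 ratio of 0.3, and was 61.0 to 62.8 with a replicate left out. The dye difference of 0.05 became 0.13 with mode centring, 0.0095 with medians over probes, 0.12 with the authors' value table, -0.11 with probes without a digest site, and 0.03 to 0.07 with a replicate left out. The cause of these shifts was not tested, apart from the restricted mixture and the dropped digest sites, whose construction removes the broad lower tail and the probes with a positive dye difference. The ratios of the named contigs kept direction and adjusted p under 0.05 in all 60 alternatives that gave them, but all 4 moved in size. SbAss10_16750 ran from -8.52 to -5.34 and SbAss10_16746 from -8.73 to -5.59, the ends being without replicate 4 and normexp. SbAss10_8027 ran from 0.96 with medians over probes to 1.36 without replicate 4. SbAss10_15049 ran from 0.96 with probes without a digest site to 1.35 without replicate 4. SbAss10_8027 has under 2 probes without a digest site, and the 2 named male-high contigs have under 2 probes above background in both channels. The lists by Muller element and by gene function were not run, because the files hold no gene names. The main test was already paired, because it tested ratios of the sexes taken within each array. Signal over background limits the lowest ratios: 60 of the 423 male-high probes were not well above background in female DNA on at least 1 array.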

Other observations

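Of the tests in this part, the swaps of female and male were set before the result was seen, and the others were chosen after it. Contigs with similar but not near-identical probes gave a view of related sequence across the female-high and not-called classes. Pairs with a male-high contig were left out. Among 373 pairs of similar contigs (from 81.8% to under 95% identity), 32 pairs were female-high in both members, 313 were called in neither, and 28 (7.51%) held a female-high and a not-called contig. Shuffling the classes over the 476 contigs gave a mean of 27.2% split pairs and a lowest value of 18.2% (permutation p = 0.0001, the smallest that 10000 shuffles can give). With each contig used once, 9.66% of 207 pairs were split, against 28.1% at random, and under 90% identity 21 of 225 pairs were split. A candidate explanation is that related contigs mostly stayed in the same dose class. The 28 split pairs would then be the ones to follow up for sequence that moved between classes. Pairs that are alleles or fragments of a single locus would raise the shared count too and were not separated. Cross-hybridization between the probes of similar contigs could raise it as well, and the shuffled contigs are not independent of each other. In the 22 female-high contigs with a similar not-called contig, the mean ratio was 0.79 ± 0.13 (SD over contigs), against 0.84 ± 0.11 in the others, a difference of -0.052 (permutation test, p = 0.03), which fits a small amount of cross-hybridization from the related sequence.

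Some contigs held probes with ratios of both classes. In 27 contigs at least 2 probes lay at 0.6 or above and at least 2 under 0.3, and 16 of these 27 were called female-high. The number of such contigs that probe noise, digest sites or cross-hybridization would give was not estimated. Along the probe numbers of these contigs the class changed 57 times, against a mean of 72.9 in shuffled order (permutation p = 0.001), and 11 contigs had a single change. By the number in the identifier, 39.0% of the contigs that followed a female-high contig were female-high too, against 16.9% of all contigs, and 52.8% of those that followed a male-high contig were male-high, against 0.619% of all contigs. Near-identical neighbours were part of this: without them the shares were 36.0% (after 1702 female-high contigs) and 37.5% (after 40 male-high contigs). The GC content of probes was 39.2 ± 2.6% (SD over contigs) in female-high contigs and 39.0 ± 2.8% in not-called contigs, a difference of 0.21 percentage points (permutation p = 0.0013, over contigs, which are not independent).

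Swapping female and male within arrays can be done in 4 ways that are not mirror images, too few for a share under 0.05. For female-high contigs 1 of the 4 ways, the real one, gave as many as 2178, and the highest other count was 0; for male-high contigs 1 of 4 gave as many as 80, and the highest other count was 0.

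Against dye bias in the contigs higher in male DNA, the 26 contigs called without replicate 4 at -3 or lower were all (100%) at -0.5 or lower on replicate 4, averaging -4.45 there. Of the 103 contigs called without replicate 4 above -3, 32 were at -1.5 or lower on the other arrays. On replicate 4 these 32 averaged -0.66 ± 0.65 (SD over contigs), with 16 at -0.5 or lower and 4 positive. Dye bias alone would turn the ratio positive there. These values argue against it as their whole cause, as far as 1 array in that orientation can. With the orientations weighted equally the 32 averaged -1.36 ± 0.46, but that mean includes the arrays that chose them. The other 71 averaged 0.15 ± 0.59 on replicate 4, where 37 were positive and 9 at -0.5 or lower, and -0.37 ± 0.38 with equal weights. For these, dye bias and a male excess cannot be told apart with a single array in the other orientation. Of these 71, 26 were among the 80 male-high contigs called with all arrays. DNA of another organism whose load differed between male pools cannot be told apart from a dye shift, because replicate 4 carried male DNA in the other dye: the median SD of the male signal of the 80 male-high contigs between the 3 pools was 0.13, but 0.35 (0.54 in the 24 contigs at -3 or lower) after the shift of not-called contigs of like male signal was taken off replicate 4, and replicates 1 and 3, in the same dye, differed by a median of 0.06 and at most 1.17. Sequence confined to or multiplied in males, as on a Y chromosome, remains a hypothesis that was not tested, as does foreign DNA at an even load.

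The ratio of the 24 contigs at -3 or lower was weaker on replicate 4 than on both other arrays in 21 of them, and averaged -4.64 ± 0.89 (SD over contigs) there against -6.66 ± 2.00 and -6.36 ± 1.80 on replicates 1 and 3. These sizes are inexact, because 54.5%, 68.3% and 83.7% of their 123 probes were well above background in female DNA on replicates 1, 3 and 4. Dye bias that grows with brightness would lower the male signal on replicate 4, as in not-called contigs of like male signal (median -0.57 on replicate 4 relative to the others). The male signal of these 24 contigs was higher there by 0.33 ± 0.19 (median, SD over contigs), but a higher load of their sequence in that male pool could offset such a shift. Their female signal was higher there by 2.18 ± 1.43 (median, SD over contigs), and part of that signal was not well above background. Their ratio shifted by 1.07 ± 0.87 (median, SD over contigs) more than in not-called contigs of like male signal. Over the 66 probes well above background in female DNA on all arrays it shifted by 0.59 ± 0.94 more. That choice drops probes with a low female signal on replicates 1 and 3, so it can itself make the shift smaller. The value over all probes rests partly on female signals near background, so neither decides and dye bias stays open. Across their 123 probes the female signal on replicate 4 followed the male signal with a slope of 0.96 ± 0.06 (bootstrap SE over contigs). On replicates 1 and 3 the slopes were 0.45 ± 0.10 and 0.53 ± 0.09. The 24 contigs lie in 14 near-identity groups, so these SEs are likely too small. Over the 66 probes the slopes were 0.72 ± 0.15 on replicate 4 and -0.00036 ± 0.21 and 0.03 ± 0.21 on the others. Choosing probes by their female signal can itself flatten a slope, as can female signals near background. A female signal that is a constant share of the male signal (a slope of 1) stays open for replicate 4. The cause of the flatter slopes was not tested. The female signal was 4.01% of the male signal on replicate 4 (geometric mean over contigs), an inexact share because not all probes were well above background there. This female signal may be a trace of male DNA in the female pool, such as stored sperm, or bleed of Cy3 into the Cy5 channel. These cannot be told apart, because only 1 array carried male DNA in Cy3.

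The dye shift of probes with a digest site was weighed against brightness and against sequence in general. Probes with a site were dimmer, but within 6 bins of brightness they still exceeded probes without a site by 0.20 to 0.53 in the dye difference, which argues against brightness alone. AGCT and GTAC shifted the median difference by 0.38 and 0.46, whereas the other 14 palindromes of 4 bases shifted it by at most 0.055. With a single AluI site, the difference was 0.49 when the site began at bases 19 to 24 of the probe and 0.08 to 0.11 at either end. This is consistent with targets cut inside the probe being labelled or retained differently for Cy3 and Cy5; no biological explanation was tested, since the shift follows the dye and not the sex.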
